A study of Mus musculus with 13 samples.

How the data were processed

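Total RNA from mouse duodenum was hybridised to 13 Affymetrix expression arrays. Per the labels, 200 ng of RNA isolated with a column kit was amplified and labelled with biotin, and the strain background was mixed. The deposited log2 values were made with Affymetrix Expression Console 1.1 by RMA (background correction, quantile normalization and summary of probes into probe sets), per the submitters' processing notes. They ranged from 1.76 to 14.2. The labels name a labelling kit for whole-transcript arrays, whereas the probe set names are those of an array that targets the 3' end of transcripts, so the labelling chemistry is not certain. The genome build behind the probe sets is not given in the sources used here, and no scanner files were used.

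Samples were grouped by the genotype and diet in their labels. The series design text calls the samples mice, and nothing else was used to decide that the replicates are separate animals, so p-values measure the spread between these samples. Array identifiers run in another number range for each diet, so diet comparisons also compare array series, while genotype comparisons lie within a series. The identifiers of wild-type and mutant high-fat array 2 also carry a number in common, whose meaning the labels do not give. In any pair of arrays at most 405 of 22690 probe sets had equal values to 3 decimals, so no array was taken for a copy.

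Of the 22690 probe sets, 64 were control probe sets, 20380 had exactly 1 gene symbol in the platform annotation, 691 had several genes and 1555 had none there. Entrez identifiers of 20351 probe sets matched the RefSeq gene table of the mouse assembly, and 0 symbols changed. For each of 12393 genes the probe set with the highest mean over the 13 arrays was tested, and 4956 genes had more than 1 probe set.

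Tests used R 4.3.3 and limma 3.58.1 (lmFit, contrasts and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment at 0.05 over all genes. Every adjusted p for a gene comes from limma. All 13 arrays entered each fit, either with 6 group means (7 residual degrees of freedom) or with diet and genotype as terms (9 residual degrees of freedom), so that the group with 1 array is assumed to vary like the others. There were 11 comparisons. Before the data were examined, 38 gene lists with 687 genes were written, of which 571 genes were measured. Of these, 36 lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The list of Xist and Y-linked genes was described only, and 1 further list and the tests that rest on it are not reported here.

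Genes were named by a rule fixed beforehand. In each comparison these were the 10 largest rises and 10 largest falls among genes past the threshold whose arrays did not overlap between groups, or, with diet as a term, whose mutant mean lay on the same side in all 3 diets. Where none passed, the 3 smallest p-values in each direction were named. Predicted and unnamed gene models were left out, and so were symbols made of a clone or accession code, an exception added later. For each list up to 4 members with the smallest p were named. For the fit without butyrate arrays the 10 largest rises and falls and the members named from its lists were chosen after their values were seen.

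The procedure was tested on simulated data with 200 changed genes among 12393. For the genotype comparison of 13 arrays it recovered 77.6% of changes of 0.5 (log2), 100% of changes of 1 and 100% of changes of 2, with 9 false calls. For the 9 arrays without butyrate it recovered 46.3%, 92.5% and 98.5%, with 10 false calls. For the genotype comparison on butyrate it recovered 7.5%, 82.1% and 92.4%, with 4 false calls. A simulated list of 20 genes shifted by 1 was called by camera, and 0 of 20 unshifted lists were. The simulated genes were drawn independently of each other, so this does not show how camera behaves where the genes of a list are correlated. Each simulated change also had the same size on every mutant array compared. The recovered shares therefore do not cover changes that differ between mutant arrays, as those on butyrate did in the real data.

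The alternatives fixed beforehand were quantile normalization of the deposited values, leaving out genes under the 30th percentile of mean level, the mean of a gene's probe sets, eBayes without trend, array weights, the arrays of the compared groups alone, the replicate number as a block, leaving out each array and, for the genotype comparison, each diet weighted equally or no butyrate arrays. For gene lists they were the estimated correlation and fry, and for named genes quantile normalization, the mean of probe sets and leaving out each array. Added after the data were seen were the mean of the acinar pancreas list as a covariate, a 2-fold minimum change, leaving out mutant butyrate arrays 1 and 3 together, follicle genes with each array left out, list tests with the covariate, after quantile normalization, with the mean of probe sets, with each array left out or without the butyrate arrays, and the alternatives of single genes in the fit without butyrate arrays. The genotype projection of an array is the sum over 200 genes of the training difference times the array's difference from the wild-type mean of its diet, divided by the sum of squared training differences.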

Results

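Gene expression was measured in the duodenum, the first part of the small intestine, of wild-type mice and of mutant mice. From 5 weeks of age the mice received a normal diet, a high-fat diet, or a high-fat diet with butyrate, a short-chain fatty acid made by gut bacteria, for 22 weeks. Each of the 13 samples was hybridised to its own Affymetrix array. There were 2 wild-type and 3 mutant arrays on normal diet, 2 and 2 on high-fat diet, and 1 and 3 on high-fat diet with butyrate. Values are the authors' RMA expression levels on a log2 scale, and array medians ranged from 6.04 to 6.14. Across genes, arrays of the same group correlated with a median r of 0.9885, and arrays of different diets with 0.9782. The number of arrays limits the precision of every comparison.

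The title of the series places the mutation and the high-fat diet together as factors in intestinal tumour formation. The genotype comparisons ask how the mutation changes the duodenum, and the diet comparisons ask how the high-fat diet and butyrate change it.

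Mutant duodenum had higher levels of Tcf23, Slit2 and Lamb3, and lower levels of Ifit1, Lyz2 and Lgr5. With diet as a term in the limma model of all 13 arrays, 127 of 12393 genes differed between 8 mutant and 5 wild-type arrays, 53 higher and 74 lower in mutants. The count was 5 with each diet weighted equally, 58 without an intensity trend and 257 with the acinar pancreas list mean as a covariate. Among the rises were Tcf23, a basic helix-loop-helix factor (log2 difference 2.63 ± 0.52 SE, 6.20-fold, adjusted p = 0.042), Slit2, a secreted guidance cue (2.39 ± 0.42, 5.25-fold), and Tm4sf4, a membrane protein (1.65 ± 0.29, 3.13-fold). Lamb3, a chain of the basement membrane protein laminin-332, rose by 1.11 ± 0.12 with adjusted p = 0.0035. Btbd3 (1.17), the glycolytic enzyme Aldoc (1.15), Prl6a1 (1.04), Rflnb (0.99), the carbonic anhydrase Car9 (0.94) and Ankrd22 (0.91) were also higher. The falls were led by Tifa, an adaptor of NF-kappaB signalling (-1.84 ± 0.33), Rps4l (-1.78), the interferon-induced GTPase Ifi47 (-1.60), Akr1c14 (-1.36) and Ifit1, an interferon-induced antiviral protein (-1.32 ± 0.16, adjusted p = 0.0079). Lyz2, a lysozyme of macrophages (-1.28 ± 0.25), Gbp8 (-1.10), Fmo1 (-1.03), Evl (-0.96) and Lgr5, a marker of crypt stem cells (2.00-fold, adjusted p = 0.0348), fell as well.

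This gene count moved with every array left out but mutant butyrate array 2, without which 138 genes passed. Leaving out any of the 9 normal or high-fat diet arrays left between 2 and 4 genes, whereas leaving out the wild-type butyrate array gave 291, mutant butyrate array 1 gave 329 and mutant butyrate array 3 gave 270. Leaving out mutant butyrate arrays 1 and 3 together, which lay near the wild-type array in these genes, gave 899 genes, all 127 among them, and all 31 genes named here or passing within a called list passed. This choice was made after their values were seen and by the same genes, so a higher count follows in part from it. Lamb3 and Ifit1 passed in all 13 fits that left out 1 array, and the other 29 of these 31 genes did not in at least 1 (adjusted p up to 0.113). Without the 4 butyrate arrays 574 genes differed between 5 mutant and 4 wild-type arrays, 278 higher and 296 lower, and 116 of them were among the 127. Leaving out each of these 9 arrays in turn gave 265 to 582 genes. The count was 265, 292 and 277 without mutant normal diet arrays 1, 2 and 3, 286 and 347 without wild-type high-fat arrays 1 and 2, and 281 without mutant high-fat array 2. Of 79 genes named from these 9 arrays or passing within a called list, 40 passed in each of the 9 fits and 39 did not in at least 1, with adjusted p up to 0.121.

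**Figure D1:**
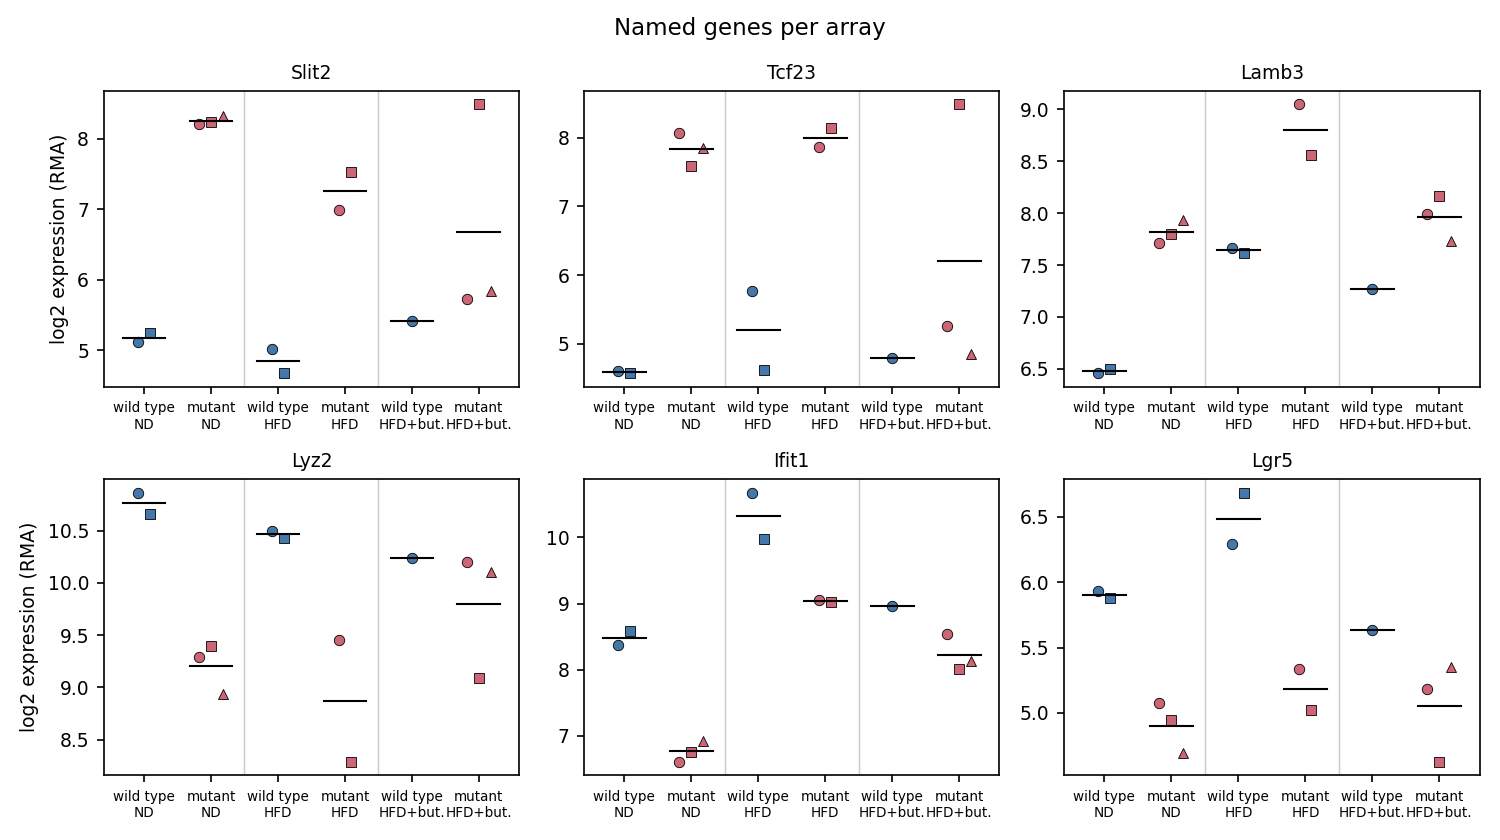
Levels of Slit2, Tcf23, Lamb3, Lyz2, Ifit1 and Lgr5 on each array in log2 units, with groups on the horizontal axis (ND, normal diet; HFD, high-fat diet; but., butyrate). Circles, squares and triangles are replicates 1, 2 and 3, and lines are group means; Slit2 was 8.49 on mutant butyrate array 2 but 5.72 and 5.84 on arrays 1 and 3, near the wild-type array at 5.42.

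In these 9 arrays Tcf23 and Slit2 were again the largest rises (3.05 ± 0.21 and 2.78 ± 0.16, 8.26-fold and 6.86-fold). Tm4sf4 rose by 1.87, the fatty acid desaturase Scd2 by 1.76 ± 0.33, the duodenal iron reductase Cybrd1 by 1.73 ± 0.41, the actin-capping protein Capg by 1.57 ± 0.19 and the alkaline phosphatase Akp3 by 1.33 ± 0.31. Btbd3 (1.33), Mboat1 (1.32) and the calcium-binding protein S100a6 (1.30) completed the 10 largest rises. The largest falls were Mptx1, a pentraxin of the intestinal epithelium (-3.13 ± 0.43, 8.73-fold), Mmp7, the protease that processes Paneth cell defensins (-2.53 ± 0.28, 5.76-fold), and Itln1, a secreted lectin (-2.48 ± 0.36). Rps4l (-2.02), Tifa (-1.87), H2-DMa (-1.87), Ifi47 (-1.84), Pipox (-1.83), Pla2g2a (-1.80) and Serpina1c (-1.80) followed.

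Single immune genes such as Ifit1, Lyz2 and Aif1 fell in mutants. Immune gene lists were lower by camera with a preset correlation, while none passed with an estimated one (adjusted p of 0.373 or more in 13 arrays). Of 21 measured interferon response genes, 4 fell in the model of 13 arrays, and 16 fell when adjusted over the list alone, with a list median of -0.75 (camera adjusted p = 1.74e-13, and adjusted p = 0.373 with an estimated correlation). In the 9 arrays without butyrate 7 fell, among them Igtp (-1.70 ± 0.42), Usp18 (-1.31 ± 0.29) and Psmb8, a subunit of the immunoproteasome (-1.11 ± 0.23). Of 23 macrophage and dendritic cell genes, 5 fell in 13 arrays, 14 when adjusted over the list alone (median -0.53, adjusted p = 3.03e-09, and adjusted p = 0.373 with an estimated correlation), and 12 in the 9 arrays. The last included Tyrobp (-1.10 ± 0.13), the complement gene C1qa (-0.96 ± 0.15), Cd68 (-0.99 ± 0.19) and Csf1r, the receptor that macrophages need for survival (-0.85 ± 0.18). None of 11 genes of MHC class II antigen presentation passed in 13 arrays, 8 fell and 1 rose when adjusted over the list alone (median -0.80, adjusted p = 1.05e-05, and adjusted p = 0.373 with an estimated correlation), and 6 fell in the 9 arrays. These were H2-DMa, H2-Ab1 (-1.79 ± 0.19), H2-Aa (-1.70 ± 0.17), Cd74 (-1.42 ± 0.18), H2-Eb1 (-1.26 ± 0.17) and Ciita, the transcription factor of this gene set (-1.07 ± 0.20). T cell and intraepithelial lymphocyte genes were lower as a list (20 genes, median -0.26, adjusted p = 0.00027, and adjusted p = 0.408 with an estimated correlation) with no single gene past the threshold in 13 arrays, over all genes or adjusted over the list alone, and 7 in the 9 arrays, including Gzma (-1.06 ± 0.23) and Cd3g (-0.95 ± 0.16). B and plasma cell genes were lower as a list (16 genes, median -0.33, adjusted p = 0.00012, and adjusted p = 0.391 with an estimated correlation), with 0 genes passing in 13 arrays, over all genes or over the list alone, and Cd79b (-0.89 ± 0.20) passing in the 9. With an inter-gene correlation estimated from the data no list passed in any comparison. With butyrate alone, where the wild type is 1 array, the macrophage, MHC class II and B cell lists were not called (camera adjusted p = 0.665, 0.484 and 0.484). The T cell list was higher in mutants there, the opposite direction (median 0.19, adjusted p = 0.00488, 0.312 without mutant array 1, and adjusted p = 0.959 with an estimated correlation). On high-fat diet the B cell list was not called (0.0701). The fry test, which asks whether a list's genes move one way, passed in 13 arrays for the interferon and macrophage lists (adjusted p = 0.0368 for each). In the 9 arrays, a fit chosen for lists after the result was seen, fry gave adjusted p = 0.0283 and 0.00666 for these. There it gave 0.00593 for MHC class II and 0.0245 for T cells, while B cells did not pass (0.0897).

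Paneth cells secrete antimicrobial proteins at the crypt base. Their markers were lower in mutants as a list by camera with a preset correlation, but not with an estimated one or with butyrate alone. None of 7 measured markers passed in 13 arrays, 4 fell when adjusted over the list alone (median -1.09, camera adjusted p = 0.00012, and adjusted p = 0.391 with an estimated correlation). In the 9 arrays Mmp7, Itln1, Pla2g2a and Lyz1, the Paneth cell lysozyme (-1.29 ± 0.27), fell. Of 17 enterocyte digestion and transport genes, 0 passed in 13 arrays, 5 fell over the list alone (median -0.25, adjusted p = 0.00019, and adjusted p = 0.391 with an estimated correlation), and 6 fell in the 9 arrays. Among these 6 were the metalloprotease Mep1a (-0.73 ± 0.14), the glucose transporter Slc2a2 (-0.60 ± 0.14) and the peptidase Dpp4 (-0.46 ± 0.10). Of 16 crypt stem cell and Wnt target genes, Lgr5 fell in 13 arrays and 2 fell over the list alone (median -0.11, adjusted p = 0.0129, and 0.391 as adjusted p with an estimated correlation). This list missed the threshold without wild-type high-fat array 1 (adjusted p = 0.0776) or wild-type normal diet array 1 (0.0512). In the 9 arrays Lgr5 (-1.14 ± 0.13) and Ascl2 (-0.90 ± 0.15) fell. Proliferation genes were lower as a list (25 genes, 0 passing, 1 lower over the list alone, median -0.16, adjusted p = 4.89e-05, and adjusted p = 0.391 with an estimated correlation), and no single member passed in the 9 arrays either. On normal diet the proliferation list was not called (adjusted p = 0.269). Its means of 8.03, 8.11 and 7.93 on mutant arrays overlapped those of 7.91 and 8.25 on wild-type arrays. It was called on high-fat diet (means 7.68 and 7.41 against 7.75 and 7.72, adjusted p = 0.000183, 0.227 without mutant array 2, and adjusted p = 0.532 with an estimated correlation) and against the single wild-type butyrate array (8.22). With butyrate the Paneth cell, enterocyte and crypt lists were not called (adjusted p = 0.922, 0.484 and 0.847).

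Genes of cholesterol synthesis and of ERK output were higher as lists in mutants by camera with a preset correlation, and not with an estimated one (adjusted p of 0.373 or more). Of 19 cholesterol synthesis genes, 0 passed over all genes in 13 arrays and 13 rose when adjusted over the list alone (median 0.49, camera adjusted p = 5.44e-10, and adjusted p = 0.373 with an estimated correlation). In the 9 arrays 5 rose, namely Fdft1, squalene synthase (0.97 ± 0.20), Fdps (0.91 ± 0.19), Mvk (0.75 ± 0.14), Mvd (0.74 ± 0.10) and Lss (0.60 ± 0.12). Of 19 ERK pathway output genes, 2 rose in 13 arrays and 7 over the list alone (median 0.09, adjusted p = 0.00491, and adjusted p = 0.391 with an estimated correlation). In the 9 arrays Spred2 (0.78 ± 0.12), Etv5 (0.66 ± 0.14), Etv4 (0.62 ± 0.13) and Spred1 (0.48 ± 0.11) rose. Spred1 and Spred2 are feedback inhibitors of the pathway, and Etv4 and Etv5 are transcription factors downstream of it. Of 21 fatty acid oxidation genes 1 rose in 13 arrays and 4 over the list alone (median 0.14, adjusted p = 0.00852, and adjusted p = 0.408 with an estimated correlation), and Cpt1a (0.54 ± 0.08), Acot1 and Acaa2 rose in the 9. The ERK and fatty acid oxidation lists were not called on normal diet (camera adjusted p = 0.208 and 0.981) or with butyrate (0.811 and 0.484). The ERK list missed the threshold without wild-type high-fat array 2 (adjusted p = 0.0542), and the fatty acid oxidation list without that array or mutant high-fat array 2 (0.0523 and 0.065). The acinar pancreas list, markers of another tissue, also had a lower median in mutants (-1.58 in 13 arrays, adjusted p = 0.00491, and adjusted p = 0.599 with an estimated correlation) with 0 of 18 genes passing, and missed the threshold without wild-type high-fat array 2, mutant high-fat array 2 or the wild-type butyrate array (0.0728, 0.138 and 0.0829), or without mutant butyrate arrays 1 and 3 together (0.0765). Its mean ranged from 5.94 to 12.56 across arrays, and from 6.47 to 12.56 among the mutants on normal diet.

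**Figure D2:**
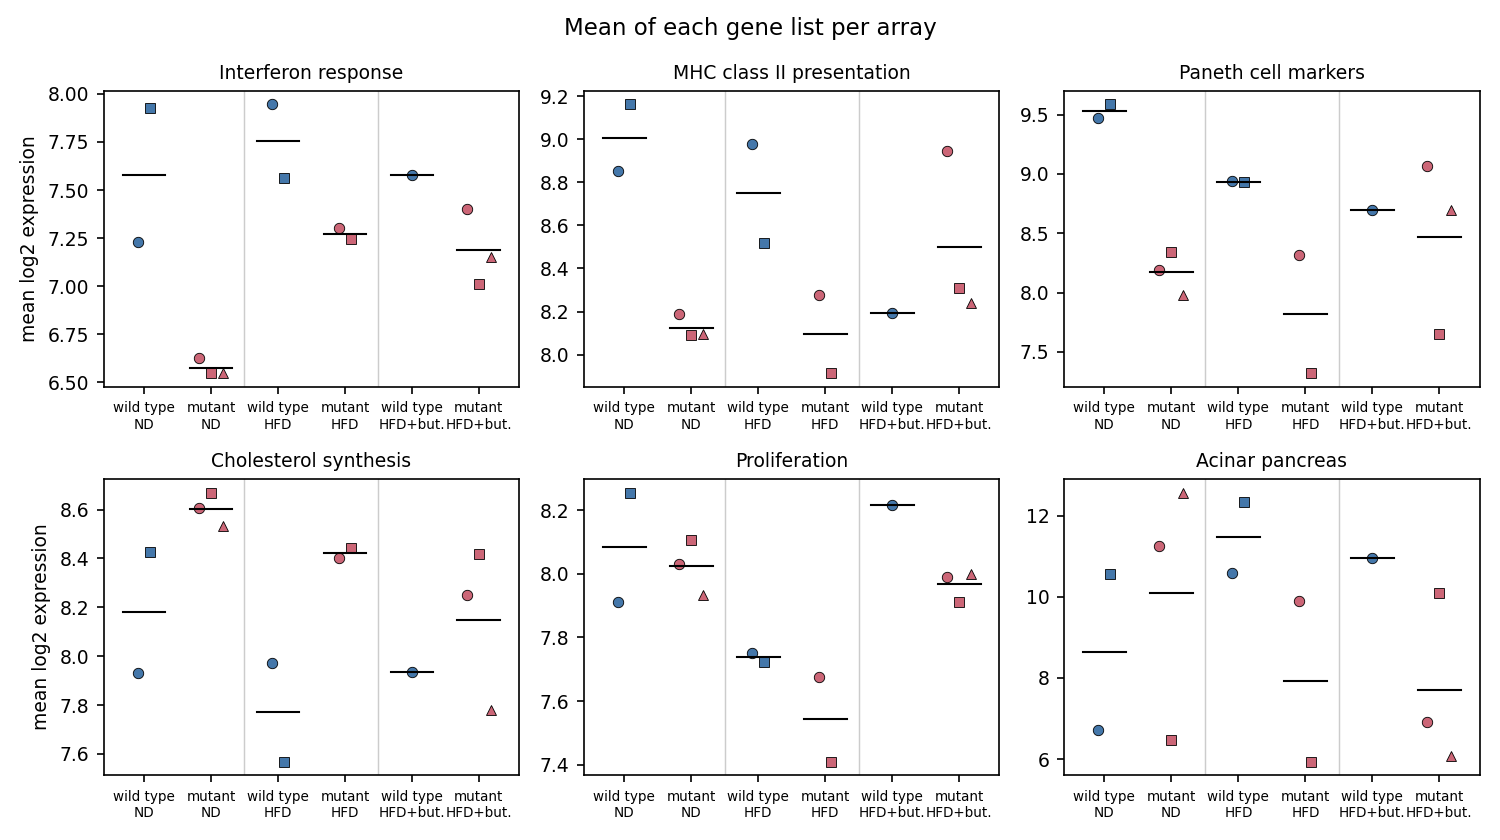
Mean log2 level of 6 gene lists on each array, with groups on the horizontal axis (ND, normal diet; HFD, high-fat diet; but., butyrate) and replicates 1, 2 and 3 as circles, squares and triangles; lines are group means. The acinar pancreas mean spans 5.94 to 12.56 without following the groups, while the Paneth cell mean is 7.65 on mutant butyrate array 2 and 9.07 and 8.69 on arrays 1 and 3.

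Within the high-fat diet, 5 genes differed between 2 mutant and 2 wild-type arrays. Array 2 of each genotype carries the same number in its identifier, and the labels do not say what it stands for. St3gal4, a sialyltransferase, was higher in mutants by 4.89 ± 0.15 (29.7-fold, adjusted p = 2.07e-08), with both wild-type arrays low (5.97 and 6.44) and the other 11 arrays between 11.10 and 12.28. It was measured by a single probe set. The DNA damage kinase Atm (1.69 ± 0.24, adjusted p = 0.048) and the insulin receptor substrate Irs2 (1.44 ± 0.18, adjusted p = 0.0165) were higher, and the unconventional myosin Myo7a (-1.93 ± 0.19) and the interferon-induced Ifi44l (-1.31 ± 0.14) were lower. St3gal4 and Myo7a passed in all 4 fits that left out an array, Ifi44l in 3 (adjusted p up to 0.0782), Atm in 1 (up to 0.313) and Irs2 in 0 (up to 0.207). The count was 3 and 8 without wild-type arrays 1 and 2, and 11 and 9 without mutant arrays 1 and 2. It was 14 with array weights and 3 with dim genes left out. Fatty acid oxidation genes were higher as a list (8 of 21 over the list alone, 0 over all genes, camera adjusted p = 1.08e-06, and adjusted p = 0.307 with an estimated correlation). Angptl4, a target of the fatty acid receptor PPAR alpha, differed by 1.74 ± 0.38 without passing alone (adjusted p = 0.161). Cholesterol synthesis genes were higher (10 of 19 over the list alone, 0 over all genes, median 0.71, adjusted p = 7.03e-09) and macrophage and dendritic cell genes lower (10 of 23 over the list alone, 0 over all genes, median -0.44, adjusted p = 3.17e-08), each with adjusted p = 0.403 with an estimated correlation. Acinar pancreas genes had a median of -4.01 in the same comparison (0 of 18 passing over all genes or over the list alone, adjusted p = 1.08e-06, and adjusted p = 0.504 with an estimated correlation).

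On normal diet, 3 genes differed between 3 mutant and 2 wild-type arrays. Ubd, an interferon-inducible ubiquitin-like modifier, was lower in mutants by -3.39 ± 0.40 (10.5-fold) and Ifit1 by -1.72 ± 0.20, and Lamb3 was higher by 1.34 ± 0.16, each with adjusted p = 0.015. Leaving out mutant array 1, 2 or 3 left 0 genes, and leaving out wild-type array 1 or 2 gave 37 or 174. Array weights gave 1, and a fit of these 5 arrays alone 36. Of 11 MHC class II genes 10 were lower over the list alone and 0 over all genes (median -1.14, camera adjusted p = 1.3e-10, and adjusted p = 0.0907 with an estimated correlation). Of 21 interferon response genes 18 were lower over the list alone and 1 over all genes (median -0.95, adjusted p = 1.09e-16, and adjusted p = 0.0907 with an estimated correlation). Of 20 T cell genes 10, of 16 B and plasma cell genes 5 and of 23 macrophage and dendritic cell genes 11 were lower over the list alone and 0 over all genes (adjusted p = 1.25e-09 for each, and 0.144, 0.124 and 0.144 as adjusted p with an estimated correlation). The MHC class II and interferon lists also passed with fry (adjusted p = 0.0138 and 0.018), as did the B cell and macrophage lists (adjusted p = 0.0371 and 0.0457).

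With butyrate, 0 genes differed between 3 mutant arrays and the single wild-type array by limma. An unadjusted p under 0.05 was found for 749 of 12393 genes, where a share of 0.05 arises without any effect. With 1 wild-type array, neither the gene nor the list tests here can separate genotype from that sample. The smallest p-values belonged to Trpc1 (-1.50 ± 0.25), Skp2 (-0.95 ± 0.16) and Mcoln3 (-2.14 ± 0.41) in the lower direction and to Tle5 (0.91 ± 0.18), Nabp2 (0.86) and Ss18l2 (0.79) in the higher, all with adjusted p = 0.428. Interferon response and proliferation genes were lower as lists (medians -0.45 and -0.30, adjusted p = 0.00488 and 0.000815), with 0 genes passing in either and 1 interferon gene lower over the list alone, and each had adjusted p = 0.959 with an estimated correlation. Cholesterol synthesis genes (median 0.19, adjusted p = 0.0185) and T cell genes (median 0.19, adjusted p = 0.00488) were higher as lists, with 0 genes passing over all genes in either and adjusted p = 0.959 for each with an estimated correlation. The cholesterol list missed the threshold without mutant array 1 or 2 (adjusted p = 0.11 and 0.41) and the T cell list without array 1 (0.312). Without arrays 1 and 3 together the T cell list had a median of -0.16 (adjusted p = 0.847), the opposite direction. Acinar pancreas genes had a median of -3.46 there (0 passing, adjusted p = 0.0025, 0.0706 without mutant array 3, 0.591 without arrays 1 and 3, and adjusted p = 0.959 with an estimated correlation). The 3 mutant arrays differed from each other in the genes named above. Tcf23 was 8.49 on array 2, against 5.26 and 4.85 on arrays 1 and 3 and 4.78 on the wild-type array. Without arrays 1 and 3, 22 genes differed between array 2 and the wild-type array, on the assumption that lone arrays vary like the other groups. Mmp7 was 6.91 on array 2, against 9.64 and 9.05 on arrays 1 and 3 and 9.04 on the wild-type array. A genotype projection over the 200 genes with the smallest p on another diet set the wild-type mean at 0 and the full difference of that diet at 1. With genes chosen on normal diet, mutant butyrate arrays 1, 2 and 3 had projections of 0.01, 0.782 and 0.033, and the 2 mutant high-fat arrays 0.652 and 0.784. With genes chosen on high-fat diet they had -0.021, 0.716 and 0.02, and the 3 mutant normal diet arrays lay between 0.519 and 0.53. Array 2 also stood apart from the other 3 butyrate arrays in control probe sets, with a 3' minus 5' difference of the spiked thr transcript of 2.88 against 3.80 to 3.92 and a ribosomal RNA level of 9.84 against 8.79 to 9.10.

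**Figure D3:**
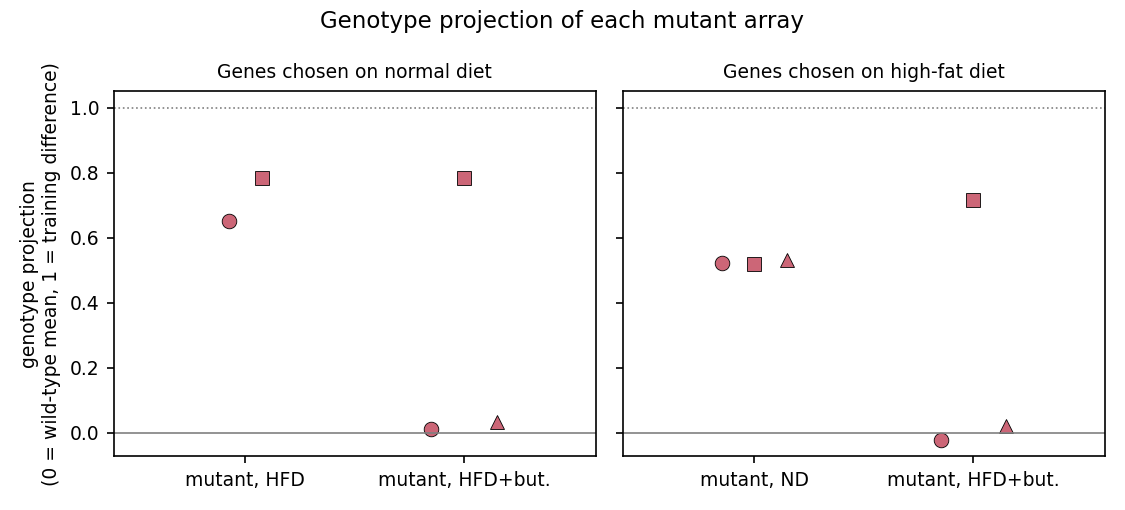
Genotype projection of each mutant array, as a share of the genotype difference in the diet on which 200 genes were chosen (normal diet at left, high-fat diet at right), for the held-out diet and for butyrate. Circles, squares and triangles are replicates 1, 2 and 3; butyrate arrays 1 and 3 lie between -0.021 and 0.033, and array 2 at 0.782 and 0.716.

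The genotype difference itself was compared between diets with interaction terms. Across genes, which are not independent replicates, the differences on normal and high-fat diet correlated with r = 0.247 (Spearman's rho 0.316, 60.1% of genes with the same sign), those on normal diet and butyrate with 0.053 (0.069, 51.1%), and those on high-fat diet and butyrate with 0.444 (0.218, 57.3%). Normal and high-fat diet were thus most alike by rank and sign, and high-fat diet and butyrate by r. Large differences of few genes can raise r. The acinar pancreas list mean differed by 1.466 on normal diet, -3.543 on high-fat diet and -3.266 with butyrate, and its part in r was not tested. St3gal4 was the 1 gene past the threshold in each interaction. There 621 and 688 of 12393 genes had an unadjusted p under 0.05, near the share of 0.05 that arises without any effect. The interaction with high-fat diet had 2 genes with quantile normalization, with the mean of probe sets or with the compared arrays alone. Without mutant butyrate arrays 1 and 3 the butyrate interaction had 2 genes, St3gal4 among them. The mutant minus wild-type difference of St3gal4 was 5.05 ± 0.20 larger on high-fat than on normal diet (adjusted p = 4.18e-07) and changed by -5.08 ± 0.23 with butyrate relative to the high-fat diet alone (adjusted p = 1.47e-06). Both values rest on the same 2 low wild-type high-fat arrays.

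The high-fat diet was compared with the normal diet within each genotype. The arrays of each diet carry identifiers of their own number range, so array series and diet cannot be told apart in these comparisons. The 3' minus 5' difference of actin lay between 0.20 and 0.42 on the 4 high-fat arrays and between 0.63 and 0.73 on the 5 normal diet arrays. The level of a ribosomal RNA control probe set lay between 11.57 and 12.05 and between 10.44 and 11.42. Zbtb7a, Slc16a3, Kdm5a and Rest were higher and Snrnp48 was lower on the high-fat diet in both genotypes and in each fit that left out an array. In mutants 2197 genes differed (951 higher, 1246 lower, 2 against 3 arrays), and in wild-type mice 1368 (696 higher, 672 lower, 2 against 2). The 2 comparisons share no array, and 512 genes rose and 497 fell in both, where independent lists would share 53.4 and 67.6. No gene passed in opposite directions.

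In mutants on the high-fat diet Cybrd1 (4.32 ± 0.73, adjusted p = 0.0029) and the iron transporter Slc11a2 (4.22 ± 0.71, 18.7-fold) rose most, followed by the transcription factor Zbtb7a (3.04 ± 0.15), the monocarboxylate transporter Slc16a3 (2.63 ± 0.20), Irs2 (2.51), the histone demethylase Kdm5a (2.50), the repressor Rest (2.45), Iqgap2 (2.31), Ifit1 (2.28) and Akap9 (2.21). The desaturase Scd1 (-2.96 ± 0.90), the glutathione transferase Gsta3 (-2.54), Pdxdc1 (-2.40), Myo7a (-2.10), the serine synthesis enzyme Phgdh (-1.92 ± 0.34), Snrnp48 (-1.84), Bbip1 (-1.76), Phip (-1.70), Cbr3 (-1.59) and Gadd45gip1 (-1.56) fell most. In wild-type mice Zbtb7a (3.29), Slc11a2 (3.16 ± 0.77), Slc16a3 (3.02), Kdm5a (2.52), Rest (2.38), Tkfc (2.32), Iqgap2 (2.16), Lrat, the enzyme that esterifies vitamin A (2.06 ± 0.20), Epn1 (1.99) and Akap9 (1.99) rose. St3gal4 (-5.98), Ubd (-3.50), the calcium-binding protein S100g (-2.43 ± 0.58), Pla2g2a (-1.94), the cytokine signalling inhibitor Socs3 (-1.92 ± 0.32), Snrnp48 (-1.86), Rasd1 (-1.79), Ttc14 (-1.76), Atm (-1.76) and Akr1b10 (-1.74) fell. With the mean of its probe sets Pdxdc1 had a difference of 0.46 in mutants, the opposite direction. In wild-type mice Slc11a2, S100g and Pla2g2a passed in 1 of the 4 fits that left out an array (adjusted p up to 0.12, 0.137 and 0.163), and in mutants Scd1 passed in 1 of 5 and Cbr3 in 2 of 5 (up to 0.166 and 0.22).

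Of 25 proliferation genes 11 fell in mutants (14 over the list alone, median -0.53, camera adjusted p = 6.89e-06, and adjusted p = 0.726 with an estimated correlation) and 3 in wild-type mice (10 over the list alone, median -0.37, adjusted p = 0.00676, and adjusted p = 0.855 with an estimated correlation). Mki67 fell by 0.80 on the log2 scale in mutants and by 0.62 in wild-type mice. Of 19 genes of chylomicron assembly and lipid uptake 4 rose in each genotype, and 6 over the list alone (adjusted p = 0.00226 in mutants and 0.00676 in wild-type mice, and with an estimated correlation adjusted p = 0.702 and 0.855). Mttp, which loads lipid onto apolipoprotein B, rose by 0.78 ± 0.10 and 0.52 ± 0.11, and the fatty acid transporter Slc27a4 by 0.57 ± 0.09 and 0.94 ± 0.10. In wild-type mice Mki67 and Mttp passed in 1 of the 4 fits that left out an array (adjusted p up to 0.0907 and 0.0819). In mutants 5 of 21 fatty acid oxidation genes rose, also over the list alone, including Acot2 (1.91 ± 0.21) and Ppara (1.11 ± 0.27), with camera adjusted p = 0.00054 and adjusted p = 0.548 with an estimated correlation. In mutants 7 of 21 interferon response genes rose (8 over the list alone, adjusted p = 3.62e-05, and adjusted p = 0.702 with an estimated correlation), including Irf7 (1.37 ± 0.16) and Oasl2 (1.42 ± 0.24). Of 8 genes of proximal intestinal position 4 rose in mutants, also over the list alone: Cybrd1, Slc11a2, Gata4 (0.84 ± 0.20) and the iron exporter Slc40a1 (1.17 ± 0.32), with adjusted p = 0.00249 and adjusted p = 0.548 with an estimated correlation. In wild-type mice B and plasma cell genes were lower (3 of 16, 4 over the list alone, adjusted p = 0.0174, and adjusted p = 0.855 with an estimated correlation), and acinar pancreas genes had a median of 3.21 with 0 passing (adjusted p = 0.033, and adjusted p = 0.855 with an estimated correlation). In wild-type mice the proliferation and chylomicron lists missed the threshold without normal diet array 2 (adjusted p = 0.437 and 0.115), the B cell list without normal diet array 1 (0.166), and the acinar list without high-fat array 2 or normal diet array 1 (0.312 and 0.523). The wild-type gene count fell to 606 or 439 without high-fat array 1 or 2, to 899 with the acinar list mean as a covariate, to 637 with array weights and to 116 in a fit of these 4 arrays alone. The mutant count fell to 990 or 1043 without high-fat array 1 or 2 and to 1245 or 1447 without normal diet array 1 or 2.

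Butyrate was compared with the high-fat diet alone, again with array series and diet not separable. On the 4 butyrate arrays the ribosomal RNA control probe set lay between 8.79 and 9.84, and the actin difference between 0.27 and 0.70. There the 3' minus 5' difference of the spiked thr transcript lay between 2.88 and 3.92, against 1.78 to 2.12 on the high-fat arrays. In mutants Zbtb7a, Kdm5a and Rest were lower and Mki67 and Bub1 higher with butyrate, in each fit that left out an array. In mutants 2685 genes differed, 1597 higher and 1088 lower with butyrate (3 against 2 arrays). The falls were led by Zbtb7a (-3.80 ± 0.15, adjusted p = 2.28e-07), Cybrd1 (-3.79 ± 0.73), Kdm5a (-3.28), the nuclear receptor corepressor Nrip1 (-3.07 ± 0.23), Akap9 (-3.04), Akp3 (-3.01), Rest (-2.99), Slc11a2 (-2.87 ± 0.71), Resf1 (-2.86) and Iqgap2 (-2.86). Clec1b (2.55 ± 0.50), Kansl1l (2.24), Myo7a (2.19), the carbonyl reductase Cbr3 (2.10), Exosc8 (2.10), Snrnp48 (2.09), Gbp8 (2.07), Phip (2.01), the haemoglobin gene Hba-a2 (1.87 ± 0.27) and Rps4l (1.86 ± 0.51) rose most. Of 25 proliferation genes 7 rose (11 over the list alone, median 0.40, adjusted p = 0.00054, and adjusted p = 0.902 with an estimated correlation), including Mki67 (0.89 ± 0.12) and Bub1 (0.90 ± 0.15). With the mean of its probe sets Phip had a difference of -0.07, the opposite direction. Rps4l passed in 1 of 5 fits that left out an array (adjusted p up to 0.138), Akp3 and Slc11a2 in 3, and Cybrd1, Clec1b and Cbr3 in 4. Mutant butyrate arrays 1 and 3, near the wild-type array in genotype genes, carried several of these changes. Rps4l was 6.60, 4.99 and 7.33 on mutant butyrate arrays 1, 2 and 3, against 4.64 and 4.25 on the high-fat mutants. Cybrd1 was 5.79, 8.72 and 5.93 against 11.44 and 9.76. Akp3 was 9.87, 12.08 and 9.18 against 13.54 and 13.23, and Slc11a2 7.46, 10.53 and 7.96 against 12.03 and 11.02. Without arrays 1 and 3, 17 of 24 genes named or passing within a called list passed, and Rps4l (0.54, adjusted p = 0.389), Cybrd1 (-1.88, 0.0772), Akp3 (-1.30, 0.216), Slc11a2 (-0.99, 0.243), Clec1b (1.41, 0.111), Mcm4 (0.54, 0.135) and Mcm7 (0.64, 0.137) did not. The count of genes was then 642, of which 600 were among the 2685, and the proliferation list kept its direction (median 0.31, adjusted p = 0.00255). Ppara fell by 2.59 on the log2 scale, and of the butyrate transport list Slc16a3 fell by 2.73 and Slc16a1 rose by 0.39 ± 0.12. The proliferation list missed the threshold without high-fat array 2 (adjusted p = 0.0639). The count was 1317 or 1456 without high-fat array 1 or 2.

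The 2 diet comparisons in mutants share the high-fat arrays, and 667 genes were higher on the high-fat diet and lower with butyrate, 912 the reverse, and 2 moved the same way in both. Independent lists would give 83.5 and 161. The differences correlated across genes with r = -0.759, where simulated arrays without effects gave -0.609 and 0 such calls, and their covariance was -0.143 against a simulated -0.0281. With 2 high-fat arrays the shared group could not be split, so part of the excess may come from it. The high-fat comparison in wild-type mice shares no array with the butyrate comparison in mutants. There 457 genes were higher and then lower and 443 lower and then higher, where independent lists would give 61.1 and 86.6, and 8 moved the same way. Both comparisons still have the high-fat array series on one side. A difference of that series would also give opposite directions, so this count cannot tell diet from series.

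The single wild-type butyrate array differed from 2 wild-type high-fat arrays in 1820 genes (1183 higher, 637 lower) in the model of all arrays, which assumes that this array varies like the other groups. St3gal4 (5.92), Mcoln3 (4.17), Snrnp48 (2.34), Exosc8 (2.34), Brwd1 (2.21), Pmaip1 (2.11), Angptl4 (2.09), Trpc1 (2.04), Kansl1l (1.98) and Clca3a1 (1.94) were the largest rises. Zbtb7a (-4.43), Resf1 (-3.57), Slc16a3 (-3.26), Rest (-3.07), Akap9 (-3.03), Tle5 (-2.92), Ankhd1 (-2.89), Klf3 (-2.85), Epn1 (-2.80) and Cpox (-2.76) were the largest falls. Pmaip1 and Clca3a1 missed the threshold in both fits that left out a high-fat array (adjusted p up to 0.0723 and 0.154), and Angptl4 without high-fat array 2 (0.0659). Of its proliferation genes 4 were higher and 9 over the list alone (adjusted p = 0.00598, and adjusted p = 0.982 with an estimated correlation). Of its T cell genes 2 were lower and 0 over the list alone (adjusted p = 0.0248, and adjusted p = 0.982 with an estimated correlation). The T cell list missed the threshold without high-fat array 1 (adjusted p = 0.252). A fit of these 3 arrays alone called 0 genes, and leaving out high-fat array 1 or 2 gave 951 or 945.

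In mutants, butyrate added to the high-fat diet was also compared with the normal diet, with 3 arrays in each group. Here 195 genes differed, 71 higher and 124 lower. Hba-a2 (1.69 ± 0.24), Ifit1 (1.47 ± 0.18, adjusted p = 0.0031), the thyroid hormone deiodinase Dio1 (1.39 ± 0.21), Exosc8 (1.30), Mpp4 (1.29), Ddx60 (1.28), the carotenoid-cleaving enzyme Bco1 (1.24 ± 0.24), Cacna1d (1.19), Dao (1.18) and Kansl1l (1.09) rose most. Chac1, a glutathione-degrading enzyme of the stress response (-3.05 ± 0.63), Clca3b (-2.40), Phgdh (-2.03 ± 0.31), Rasal2 (-1.92), the sterol transfer protein Stard4 (-1.73 ± 0.14), Cnot6l (-1.68), Kif5b (-1.64), Dusp8 (-1.61), Ppara (-1.48) and Klf9 (-1.46) fell most. Interferon response genes were higher as a list (1 of 21 over all genes, 10 over the list alone, adjusted p = 9.12e-08, and adjusted p = 0.653 with an estimated correlation). Cholesterol synthesis genes were lower (1 of 19, 4 over the list alone, median -0.42, adjusted p = 9.1e-06, and adjusted p = 0.653 with an estimated correlation). Genes of ERK output (1 of 19 lower, also 1 over the list alone, median -0.22, adjusted p = 0.00638) and of the unfolded protein response (1 of 17 lower, 4 over the list alone, median -0.14, adjusted p = 0.0191) were lower as lists, each with adjusted p = 0.653 with an estimated correlation. Higher as lists were macrophage and dendritic cell genes (1 of 23, 4 over the list alone, median 0.27, adjusted p = 0.00364), MHC class II genes (0 of 11, also 0 over the list alone, median 0.62, adjusted p = 0.0206) and fatty acid oxidation genes (1 higher and 1 lower of 21, 3 and 1 over the list alone, median 0.15, adjusted p = 0.00931), each with adjusted p = 0.653 with an estimated correlation. Genes of chylomicron assembly were higher too (1 of 19, also 1 over the list alone, median 0.10, adjusted p = 0.0345, and adjusted p = 0.765 with an estimated correlation). The MHC class II list missed the threshold without normal diet array 3 or mutant butyrate array 1 (0.0571 and 0.137), fatty acid oxidation without mutant butyrate array 2 (0.151), and chylomicron assembly without normal diet array 1 or 3 or mutant butyrate array 3 (0.107, 0.112 and 0.0868). Acinar pancreas genes had a median of -2.52 (0 passing, adjusted p = 0.00364, and adjusted p = 0.89 with an estimated correlation). The ERK list missed the threshold without mutant butyrate array 3 (adjusted p = 0.071), and the acinar list without that array or normal diet array 3 (0.071 and 0.182). The ERK list mean was 6.20, 6.49 and 6.12 on mutant butyrate arrays 1, 2 and 3, against 6.51 to 6.55 on the normal diet mutants. The cholesterol synthesis mean was 8.25, 8.42 and 7.78 against 8.53 to 8.67. Without mutant butyrate arrays 1 and 3 together the interferon and fatty acid oxidation lists passed (adjusted p = 3.31e-05 and 5.32e-05), while ERK output (median -0.06, adjusted p = 0.82), cholesterol synthesis (-0.10, 0.166), MHC class II (0.508), macrophages (0.428), chylomicron assembly (0.138), the unfolded protein response (0.138) and acinar pancreas (0.543) did not. Of 24 genes named or passing within a called list, 15 were lost in at least 1 fit that left out an array, among them Chac1 (adjusted p up to 0.156), Bco1 (0.133) and Phgdh (0.0604). Without mutant butyrate arrays 1 and 3, which leaves 1 array, 4 of the 24 passed, namely Stard4, Cnot6l, Kif5b and Klf9. The count was 627 without mutant butyrate array 2. It was 44 and 66 without arrays 1 and 3, 27 without both (20 of the 195 among them), 64, 45 and 39 without normal diet arrays 1, 2 and 3, 63 with the acinar covariate and 623 with array weights.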

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

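The tests of the spiked thr transcript, of acinar genes by genotype, of an atypical wild-type butyrate array and of a like lowering by butyrate in all mutants were chosen only after the result was seen, as were the gene list tests without butyrate arrays, with each array left out or without mutant butyrate arrays 1 and 3.

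The genotype difference of St3gal4 differed between diets. It was 5.05 larger on high-fat than on normal diet and changed by -5.08 with butyrate relative to the high-fat diet alone. Both values rest on the same 2 wild-type high-fat arrays, with a mean of 6.21 against 11.1 on the high-fat mutants and 12.13 on the wild-type butyrate array. Leaving out 1 of these 2 arrays keeps the other low value, so such fits do not test the difference. The gene was measured by a single probe set.

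Gene lists also differed in their genotype difference between diets by camera with a preset correlation, and none did with an estimated correlation (adjusted p of 0.41 or more for 8 lists from normal to high-fat diet, and of 0.587 or more for 9 lists with butyrate). Each change below is the median, over the genes of a list, of the change in genotype difference. From normal to high-fat diet the genotype difference changed by 0.35 for MHC class II presentation, 0.21 for fatty acid oxidation and 0.27 for T cells. It changed by 0.49 for B and plasma cells and by 0.49 for interferon response. It changed by -0.35 for fibroblasts and extracellular matrix, -5.35 for acinar pancreas and -1.05 for stomach and Brunner gland genes, and 0 of these 8 lists passed with an estimated correlation. Fatty acid oxidation and acinar pancreas genes passed in each fit that left out an array, and the other 6 lists did not, with adjusted p up to 0.903 for stomach and Brunner gland genes without wild-type high-fat array 1, and 0.358 for interferon response and MHC class II without wild-type normal diet array 2. T cells (0.29) and fibroblasts (0.647) missed the threshold most without wild-type high-fat array 2 and wild-type normal diet array 2, and B cells without mutant high-fat array 1 (0.104). From high-fat diet alone to added butyrate the genotype difference changed by -0.33 for ERK output, 0.97 for MHC class II, 0.25 for crypt and Wnt targets, -0.19 for fatty acid oxidation, -0.48 for cholesterol synthesis, 0.51 for T cells, 0.21 for B and plasma cells, 0.28 for macrophages and 0.93 for stomach and Brunner gland genes, and 0 of these 9 lists passed with an estimated correlation. MHC class II, fatty acid oxidation, T cell and macrophage lists passed in each fit that left out an array. ERK output and cholesterol synthesis missed the threshold most without wild-type high-fat array 2 (0.176 and 0.17), crypt and Wnt targets and stomach genes without wild-type high-fat array 1 (0.272 and 0.693), and B cells without mutant high-fat array 2 (0.363). The wild-type side rests on 1 butyrate array. Without mutant butyrate arrays 1 and 3 together MHC class II, T cells and macrophages passed (0.019, 0.0357 and 0.0455) and the other 6 did not (adjusted p from 0.145 to 0.738), with a median of 0.10 for ERK output. Of the 1555 probe sets without a gene name, 31 differed between genotypes without the butyrate arrays, 13 of them higher in mutants, and 1 differed in 13 arrays.

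Other groupings of the arrays were compared with the real ones. Genotype was labelled within diets in 100 of 240 possible ways, the real one among them. Of these, 2 gave 127 genes or more, and 1 of the 2 was the real labelling, which gave 127. This share under 0.05 argues against chance for the labels as a set without excluding it. The highest other count was 139, with the wild-type butyrate array and mutant butyrate array 3 exchanged, so the count does not bear out the labels of those arrays. Only 2 other relabellings called any gene. Without the butyrate arrays 1 of 60 relabellings, the real one, gave 574 genes and the highest other gave 1, a share under 0.05 that argues against chance. For butyrate against normal diet in mutants 1 of 10 splits, the real one, gave 195 genes and the highest other gave 1, and 10 splits are too few for a share under 0.05.

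Mutant butyrate arrays 1 and 3 had genotype values near the wild-type butyrate array, while array 2 resembled mutants of the other diets and stood apart from the other 3 butyrate arrays in labelling controls (thr 2.88 against 3.80 to 3.92, ribosomal RNA 9.84 against 8.79 to 9.10, GAPDH 3' minus 5' -0.13 against 0.07 to 0.22) and in the proximal position list (mean 8.10 against 6.96 to 7.15). Array 2 differed from the mean of arrays 1 and 3 by at least 0.716 of the genotype difference. An atypical wild-type array would shift all 3 projections alike, so it cannot account for this gap. Because the wild-type array drops out of the gap, the gap cannot decide whether that array is atypical, which stays open. Differences in acinar RNA as the whole account were argued against, with a gap of 0.495 after the acinar slope was removed. That gap, with genes chosen on high-fat diet, was smaller than 0.716. Arrays 1 and 3 then had projections of 0.163 and 0.239, and of 0.149 and 0.22 with genes chosen on normal diet. The slope was fitted within groups on arrays that include these 3 mutant butyrate arrays. Part of the shrinkage may therefore come from the fit itself, and it cannot show a part from acinar RNA, which stays open. A lowering by butyrate alike in all 3 mutants was argued against, since their projections ranged over 5.848 times those of held-out mutant arrays. A wrong label on arrays 1 and 3 stays open, since exchanging array 3 with the wild-type array gave 139 genes against 127, and so does a technical difference of array 2, which these arguments leave aside. A lowering by butyrate that differs between mice may give the same values and was not tested, and no array was regrouped.

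Diet comparisons coincide with array series. A signal that depends on the probe set stays open on the following values. Of 1579 genes with opposite changes in both mutant diet comparisons, 476 had a second probe set above a minimum level. In 390 of these 476 it moved the same way between high-fat and normal diet (81.9%, exact interval 78.2% to 85.3%). The butyrate comparison was not checked in this way. The share was 89.6% for genes higher on the high-fat diet (155 of 173) and 77.6% for those lower (235 of 303, 72.4% to 82.1%). For genes called between genotypes without the butyrate arrays it was 98.6% (145 of 147). Labelling or hybridisation may differ between series, since in the butyrate series the 3' minus 5' difference of the spiked thr transcript was 2.883 or more against at most 2.118 elsewhere, a range 2.181 times the largest within a series. The high-fat and normal diet arrays overlapped in this measure but not in the 3' minus 5' difference of actin (0.20 to 0.42 against 0.63 to 0.73) or a ribosomal RNA control probe set (11.57 to 12.05 against 10.44 to 11.42). The effects of diet themselves cannot be told apart from those of array series.

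Acinar pancreas genes varied between arrays of a group. A change that follows genotype was not shown and stays open. The list mean differed by 1.466 on normal diet, -3.543 on high-fat diet and -3.266 with butyrate (exact permutation p = 0.375 within diets). The opposite sign on normal diet lies within the spread there, with 11.25, 6.47 and 12.56 on mutant arrays and 6.7 and 10.55 on wild-type arrays. Pancreatic tissue in the sample may contribute, but 3 measured islet genes correlated with the acinar list within groups with r = 0.492 (12 arrays, permutation p = 0.1) and rho = 0.448 (permutation p = 0.15). Without the 2 farthest arrays r was 0.051, so the relation rests on those arrays and the source stays open.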

How the results depend on the processing

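The acinar covariate, the 2-fold minimum, leaving out mutant butyrate arrays 1 and 3 together, the settings for gene lists other than estimated correlation and fry, and all settings for single genes of the 9-array fit were chosen only after the result was seen. For the genotype comparison with diet as a term (127 genes) no trend gave 58, each diet weighted equally 5, no butyrate arrays 574, the acinar covariate 257 and the 2-fold minimum 15, and leaving out an array gave 2 to 329. Within the high-fat diet (5 genes) leaving out dim genes gave 3, array weights 14, and leaving out an array 3 to 11. On normal diet (3 genes) array weights gave 1, the compared arrays alone 36, and leaving out an array 0 to 174. The interaction of genotype with high-fat diet (1 gene) had 2 with quantile normalization, 2 with the mean of probe sets, 2 with the compared arrays alone and 1 to 10 when an array was left out, and that with butyrate (1 gene) had 1 to 2 when an array was left out. For the high-fat diet in wild-type mice (1368 genes) array weights gave 637, the compared arrays alone 116, the acinar covariate 899, the 2-fold minimum 220 and leaving out an array 439 to 1520. In mutants (2197 genes) the 2-fold minimum gave 258 and leaving out an array 990 to 1522. For butyrate against high-fat diet in mutants (2685 genes) the 2-fold minimum gave 395 and leaving out an array 1317 to 3041. In wild-type mice (1820 genes) the compared arrays alone gave 0, the 2-fold minimum 522 and leaving out an array 945 to 951. For butyrate against normal diet in mutants (195 genes) array weights gave 623, the acinar covariate 63, the 2-fold minimum 49 and leaving out an array 39 to 627. Without mutant butyrate arrays 1 and 3 together the count was 899 for genotype with diet as a term, 22 for genotype with butyrate (0 genes with all arrays), 2 for the interaction with butyrate, 642 for butyrate against high-fat diet and 27 for butyrate against normal diet in mutants. Fewer arrays or a size minimum are part of some of these settings, and for the others the cause was not tested. Leaving out an array that leaves a lone sample assumes that it varies like the other groups, and the wild-type butyrate array could not be left out of its own group's comparisons.

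With the replicate number as a block the count was 2 for genotype with diet as a term, 36 on high-fat diet, 7 on normal diet, 867 and 1411 for the high-fat diet in wild-type mice and mutants, and 95 for butyrate against normal diet in mutants. The numbers were not taken to pair the arrays, since the only set of 3 pairs, mutants on normal diet and butyrate, deviated with r = 0.129, -0.307 and -0.253. The sets of 2 pairs, too few to decide, gave -0.243 and -0.326 for the normal diet genotypes, 0.28 and 0.416 for mutants on high-fat and normal diet, 0.012 and 0.012 for the high-fat genotypes, 0.032 and 0.032 for wild-type mice on high-fat and normal diet, and 0.064 and -0.161 for mutants on high-fat diet and butyrate.

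Of 261 tests of named genes, 257 kept direction and significance with quantile normalization and 4 lost significance. With the mean of probe sets 244 did, 15 lost significance and 2 reversed, Pdxdc1 to 0.46 on the high-fat diet and Phip to -0.07 with butyrate, both in mutants, and the cause was not tested. In each fit that left out an array 135 did. Of 87 list calls, 0 passed with an estimated correlation and 11 with fry, and 82 kept theirs with quantile normalization, 80 with the mean of probe sets, 74 of 81 with the acinar covariate and 16 of 18 without the butyrate arrays. Without mutant butyrate arrays 1 and 3, 53 of 80 tests of named genes and 24 of 42 list calls kept theirs, 27 and 17 missed the threshold, and T cell genes between genotypes with butyrate reversed (adjusted p = 0.847), for which the cause was not tested. With each array left out 43 passed in every fit, 44 did not, and 1 turned direction, enteroendocrine markers on high-fat diet without mutant array 2. RMA had already quantile normalized the deposited values, so doing so again could change little and is a weak check. The mean of probe sets changes the values of only the 4956 of 12393 genes with more than 1 probe set. Signal over background was not used here, so how it limits dim genes is not known.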

Other observations

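The medians of gene lists without butyrate arrays, and of follicle genes with each array left out, were chosen only after the result was seen, while the tests of cholesterol synthesis genes and of follicle genes in all 9 arrays were not.

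Further gene lists were lower in mutants with diet as a term in 13 arrays. Fibroblast and extracellular matrix genes had a median difference of -0.21 (1 of 18 lower, 4 over the list alone, camera adjusted p = 0.000431, and adjusted p = 0.391 with an estimated correlation). Enteroendocrine markers had -0.19 (0 of 15, adjusted p = 0.0187), antimicrobial lectins -0.15 (0 of 16, adjusted p = 0.0396), genes of epithelial to mesenchymal transition -0.13 (0 of 16, 1 over the list alone, adjusted p = 0.0347) and inflammatory cytokines and NF-kappaB targets -0.09 (1 of 23, 2 over the list alone, adjusted p = 0.0473). With an estimated correlation adjusted p was 0.582 for enteroendocrine markers and 0.391 for the other 3. Within a diet the fibroblast, enteroendocrine and transition lists were not called on normal diet (camera adjusted p = 0.273, 0.299 and 0.299), nor antimicrobial lectins and NF-kappaB targets on high-fat diet (0.14 and 0.53). With butyrate none of these 5 was called (adjusted p from 0.176 to 0.922), so each was called within 1 diet. Of these lists the fibroblast list passed in each fit that left out an array. Antimicrobial lectins missed the threshold most without wild-type normal diet array 2 (adjusted p = 0.526), NF-kappaB targets without wild-type normal diet array 1 (0.182), and the enteroendocrine and transition lists without mutant high-fat array 2 (0.335 and 0.126).

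The following lists did not pass. The median difference was 0.09 for tuft cells (adjusted p = 0.442), 0.06 for chylomicron assembly (0.142), 0.04 for neutrophils and mast cells (0.882), 0.04 for stomach and Brunner gland (0.655), 0.25 for proximal position (0.115), 0.05 for immediate early and heat shock genes (0.741), 0.07 for erythroid genes (0.471) and 0.07 for butyrate transport (0.302). It was -0.04 for smooth muscle (0.471), -0.10 for endothelium (0.471), -0.004 for enteric neurons and glia (0.577), -0.04 for distal position (0.562), -0.06 for the circadian clock (0.348) and -0.009 for the unfolded protein response (0.276). In 4 lists the median and the test differed in sign, namely goblet cells (0.04, 0.223), fatty acid synthesis (-0.006, 0.983), xenobiotic metabolism (-0.003, 0.948) and adipose tissue (-0.06, 0.945). Xist lay between 10.51 and 11.87 on all 13 arrays, and Eif2s3y, Kdm5d and Uty between 2.15 and 3.42.

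One hypothesis was that acinar RNA could account for the higher cholesterol synthesis genes in mutants. With the acinar covariate their median in the 9 arrays was 0.564 against 0.591 without it, or 95.38%, which argues against it.

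Fewer lymphoid follicles in the mutant samples might lower immune cell genes. The follicle genes Cr2, Cxcr5, Fcer2a, Cd22 and Ms4a1 had a median of -0.321 in the 9 arrays, against -0.575 for the macrophage and dendritic cell list, and none of these 5 genes passed (adjusted p from 0.187 to 0.859). Without wild-type normal diet array 1 the follicle median was -0.05 against -0.501 for macrophages, and without any other array between -0.471 and -0.282, so the fall of follicle genes rests on that array and this stays open.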
